A study of Mus musculus with 8 samples.

How the data were processed

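Gene counts of 8 libraries of mouse embryonic stem cells were used as deposited: integer counts per gene, which per the submitters' processing notes came from QuantSeq 3′ mRNA reads trimmed with Trim Galore and aligned to GRCm38. The version of the trimmer, the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The table held 55421 gene identifiers, of which 99.5% had a symbol in the annotation used here and 267 had none. Library totals lay between 8326675 and 12726123 counts. The 8 libraries form 4 groups of 2: untreated wild-type cells and cells with a knockout (KO) of the microRNA cluster from Mir290a to Mir295, prepared as one set, and KO cells with the negative control or the Tfap4 siPOOL (5 nM, 36 hours), prepared as another. Each comparison stays within a set and the comparisons share no library.

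Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, which left 15137, and scaled with TMM factors. A quasi-likelihood model (robust, not the legacy fit) with 4 group means was fitted to all 8 libraries, with 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM, and log2 CPM for list tests used a prior count of 2, both computed here from the counts. A fold against a group at 0 was bounded with 3 counts over that group. The 24 gene lists were fixed before the data were examined and held 355 entries, of which 353 were in the table and 300 were tested. They cover reported targets of the microRNA family, genes reported to respond to TFAP4, naive and primed pluripotency, ectoderm, mesoderm, endoderm, trophectoderm, the 2-cell-like state, fibroblast or feeder cells, WNT, TGF-beta and p53 targets, G1/S, MYC and ribosome biogenesis, glycolysis, interferon response, stress response and amino acids, cholesterol, the microRNA pathway, mesenchymal and epithelial markers, imprinted genes and DNA methylation. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry.

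The genes named were Tfap4, the genes at the cluster, the 8 largest rises and 8 largest falls with a mean of at least 10 CPM and no overlap between groups, up to 4 called members of each list (or the 2 most abundant where none was called), and the 6 genes with the largest opposite changes. A gene that this rule selects is not reported here. Sites for the shared seed were searched in the longest annotated 3′ UTR of each gene, which 12781 tested genes had, and a linear model over genes used log2 3′ UTR length and GC as covariates. Overlaps of called genes were tested with Fisher's exact test, two-sided. The share of a gene's last 200 bases whose words of 31 bases also occur in other genes was computed, and genes above 50% are treated as uncertain. A search of promoters for E-boxes was planned and not run, since no genome sequence was used here.

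Alternatives were DESeq2 1.42.0 size factors and Wald test, limma-voom, the legacy quasi-likelihood fit, 2 other filters on low counts, the 4 libraries of a comparison alone, a threshold of 0.1, the replicate number as a block, and each library left out in turn. The lone library of a group is then assumed to vary like the others. A correction for the GC percent of the last 100 bases (a lowess curve per library with a span of 0.3, used as an offset) was added after seeing the data, alone and with the replicate block, as was a model with squared covariates. The fit was tested on simulated data. Of genes set to change by 4-fold, 86% and 81% were called in the KO and siTfap4 designs, and of those set to change by 2-fold 25% and 22%, so smaller changes are mostly missed at this depth and replication. The genes set to change did not include those with the lowest levels, where recovery was not tested. False calls among unchanged genes numbered 7 and 11, where 14689 and 14639 genes were tested, counting those set to change. With a simulated trend in GC false calls numbered 174 of 14667 and 114 of 14638, and 18 and 6 after the correction for base composition. The simulated trend was linear and the same in both libraries of a group, while the siNeg duplicates differed in their trend. The simulation therefore does not show how many calls such a trend gives in the data.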

Results

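Gene expression was measured by sequencing the 3′ ends of polyadenylated RNA in mouse embryonic stem cells of the E14 line, grown on gelatin with serum and LIF. The 8 libraries form 4 groups of 2 biological duplicates each. Wild-type cells (WT) and cells lacking the microRNA cluster that runs from Mir290a to Mir295 (KO) were untreated, and their libraries were prepared and sequenced as one set. KO cells transfected for 36 hours with 5 nM of a pool of small interfering RNAs against Tfap4 (siTfap4) or of a negative control pool (siNeg) made up the other set. The cluster holds the most abundant microRNAs of these cells, several of which share the AAGUGC seed, and Tfap4 encodes a transcription factor that binds E-box sequences. Total counts per library were 12163759 and 9925557 in WT, 12726123 and 11764868 in KO, 11395211 and 10795092 in siNeg, and 8326675 and 8829051 in siTfap4. Between 19271 and 21183 genes had at least 1 count in a library. Levels are CPM scaled with TMM factors, given as mean ± SD over n = 2 libraries. The p-values of single genes measure spread between duplicates pooled over the 4 groups, so each comparison also uses the spread of the other set. That spread was above counting error in every group. The chi-square per degree of freedom was 20.1 in WT, 11.9 in KO, 39.5 in siNeg and 31.5 in siTfap4, so it was larger in the siPOOL set. The p-values of camera and of Fisher's exact test compare sets of genes.

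Tfap4 was higher in KO than in WT cells and lower after its knockdown. The gene (ENSMUSG00000005718) lies on the minus strand of chromosome 16 at 4544661 to 4559854 in GRCm38. Its level was 18.0 ± 2.32 CPM in WT and 45.5 ± 4.91 CPM in KO cells, a log2 fold change of 1.33 (SE 0.26). It was 35.9 ± 2.06 CPM in siNeg and 14.1 ± 2.44 CPM in siTfap4, a log2 fold change of -1.35 (SE 0.27). The counts were 242 and 169 in WT, 641 and 510 in KO, 402 and 386 in siNeg, and 97 and 134 in siTfap4. The adjusted p was 0.00363 for KO against WT and 0.00365 for siTfap4 against siNeg. The first call was lost without KO replicate 1 (log2 fold change 1.22, adjusted p = 0.0547), and the second without siTfap4 replicate 1 (log2 fold change -1.18, adjusted p = 0.0602). The 3′ UTR of Tfap4 holds 1 match to AGCACTT and 1 match to GCACTTA. These words overlap and were counted separately, so both matches can lie in the same AGCACTTA. Whether they do was not tested.

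Counts over the plus-strand entries of the deleted cluster were seen in WT cells alone. The plus-strand entries from Mir290a to Mir295, on chromosome 7 between 3218626 and 3220841, held 88 and 39 counts in the WT libraries and 0 in all 6 libraries of KO cells. Against a floor of 3 counts over the KO group this is at least 46.9-fold higher in WT, and the floor covers counting error only. Of these entries, Mir295 held 80 and 22 of the WT counts. The neighbouring AU018091, at 3154658 to 3169203, stood at 132 ± 10.6 CPM in WT and 132 ± 20.6 CPM in KO cells (log2 fold change 0.00, adjusted p = 0.999). On the minus strand, Mir290b, which overlaps Mir290a, held 4 counts in KO replicate 1 and 0 in the other 7 libraries. Nlrp12, which overlaps part of the cluster on the minus strand, held 161 counts in KO replicate 1 and 0 or 1 in the other 7 libraries. AU018091 was also called lower in siTfap4 than in siNeg (log2 fold change -0.73, adjusted p = 0.0438), a call lost without siNeg replicate 1 (adjusted p = 0.157), siNeg replicate 2 (0.0670) or siTfap4 replicate 1 (0.244), when the 4 libraries of this set were fitted alone (0.0952), and with a correction for base composition at the 3′ end (0.199).

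**Figure D1:**
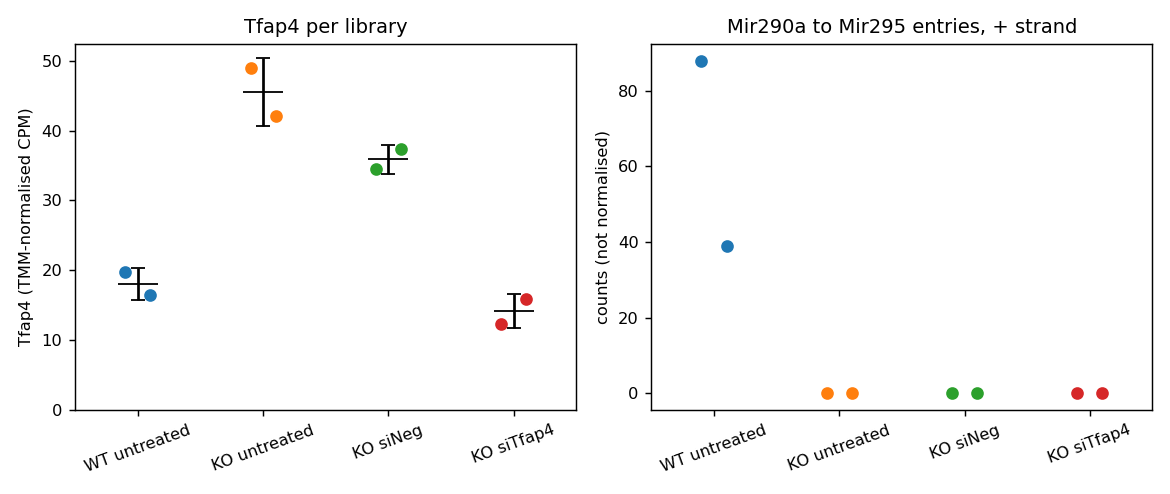
Left, Tfap4 in each library (CPM scaled with TMM factors), with the mean and SD of each group of 2 libraries; right, raw counts over the plus-strand entries from Mir290a to Mir295. Tfap4 averaged 45.5 CPM in KO and 18.0 CPM in WT cells, and the cluster entries held 88 and 39 counts in WT against 0 elsewhere.

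The comparison of KO with WT cells asks which transcripts differ between cells without and with the cluster. No group restores the cluster, so effects of its loss cannot be told apart here from other differences between KO and WT cells. Among the largest rises, Hhip, an antagonist of hedgehog ligands, stood at 98.7 ± 10.8 CPM in KO and 1.99 ± 0.06 CPM in WT cells, 49.3-fold higher. Lefty1, a Nodal antagonist, was 36.6-fold higher in KO cells (200 ± 13.4 against 5.30 ± 5.72 CPM), and the inhibin subunit gene Inhbe 47.7-fold (27.9 ± 3.44 against 0.575 ± 0.009 CPM). The homeobox genes Rhox9 and Rhox6 were 39.9-fold and 32.7-fold higher. Over the leave-outs the log2 fold change ran from 4.71 to 6.60 for Rhox9 and from 4.31 to 5.65 for Rhox6. Among the largest falls, Dab2, an endocytic adaptor, was 20.9-fold lower in KO cells (1.26 ± 0.38 against 26.7 ± 2.05 CPM) and the collagen gene Col4a1 15.6-fold lower (3.86 ± 0.38 against 60.2 ± 0.98 CPM).

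In edgeR, 1506 of the 15137 tested genes differed between KO and WT cells: 907 rose and 599 fell, and 1333 of them by at least 2-fold. The count was 857 without WT replicate 1, 774 without WT replicate 2, 610 without KO replicate 1 and 681 without KO replicate 2. When the 4 libraries of this set were fitted alone, 1861 genes were called, of which 1114 rose and 747 fell. Among well-expressed genes whose groups did not overlap, the other large rises were Cyp4f40, a cytochrome P450 gene (log2 fold change 5.49, SE 0.46), Serpinf1, which encodes a secreted serpin (5.23, SE 0.39), and the kinase gene Cdk15 (4.90, SE 0.47). Adjusted p-values of the 8 largest rises ran from 7.44e-08 for Hhip to 0.000276 for Lefty1. The falls included the small nucleolar RNA genes Snora20 (-3.70, SE 0.43) and Snord13 (-3.58, SE 0.50), Serpine2, a secreted protease inhibitor (-2.90, SE 0.34), and Prps2, a nucleotide synthesis enzyme (-2.80, SE 0.29). Pros1 and Gas6, which encode related ligands of the TAM receptors, fell as well (-2.82, SE 0.36, and -2.76, SE 0.38). Adjusted p-values of the 8 largest falls ran from 2.21e-05 for Prps2 to 0.000777 for Snord13. All 16 of these calls held when any 1 of the 4 libraries was left out. Of the last 200 bases of Inhbe, 21.8% are shared with other genes.

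Endoderm markers fell together in KO cells. Of 13 tested members, 8 fell and 0 rose, and adjusted over the list alone the counts were the same. Besides Dab2 and Col4a1, the endoderm transcription factor gene Gata6 was 10.2-fold lower (1.36 ± 0.52 against 13.8 ± 2.66 CPM) and the laminin gene Lama1 4.76-fold lower (10.6 ± 1.51 against 50.4 ± 14.5 CPM). The list was called lower by camera (adjusted p = 1.56e-07; adjusted p = 0.0790 with an estimated correlation). Other lineage markers were mixed. The neural regulator Pax6 rose (log2 fold change 5.11, SE 0.53), the sole one of 6 ectoderm and neural genes to change. Of 11 trophectoderm genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Tfap2c, an AP-2 factor gene, 3.41-fold higher (adjusted p = 0.00173). Of 5 mesoderm and primitive streak genes, Cdx1 fell (-1.42, SE 0.37), a call lost without WT replicate 2 (adjusted p = 0.237), KO replicate 1 (0.117) or KO replicate 2 (0.176). Camera did not call these lists: adjusted p was 0.255 for ectoderm, 0.189 for trophectoderm and 0.626 for mesoderm. The trophectoderm list was called without KO replicate 1 (adjusted p = 0.0336).

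Genes reported as targets of this microRNA family, and genes of the TGF-beta, Nodal and BMP pathways, rose on balance in KO cells. Of 19 reported targets, 5 rose and 1 fell (8 and 2 adjusted over the list alone). The risers included Lefty1, Lefty2, which encodes another Nodal antagonist (10.7-fold, 168 ± 24.9 against 15.5 ± 6.32 CPM), and Mbd2, a methyl-CpG binding protein gene (0.90, SE 0.26). Btg2, an antiproliferative gene, fell (-1.22, SE 0.25). The list had a camera adjusted p of 0.0174, with adjusted p = 0.265 with an estimated correlation, and 0.0542 without KO replicate 2. Of 14 TGF-beta, Nodal and BMP genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone). Lefty1 and Lefty2 belong to this list too, with Skil, a SMAD repressor gene, which rose by 1.16 (SE 0.25), while Bmp4, a BMP ligand gene, was 2.91-fold lower (207 ± 3.48 against 602 ± 16.9 CPM). Its camera adjusted p was 0.0333 (adjusted p = 0.471 with an estimated correlation), and 0.113 without WT replicate 2 or 0.0785 without KO replicate 2. It was 0.0675 on the 4 libraries of this set alone and 0.107 with fry. Lefty1, Lefty2 and Bmp4 kept their calls without any 1 library. Mbd2 lost its call without any 1 of the 4 libraries (adjusted p 0.136 to 0.289), Btg2 without WT replicate 1 (0.0663), KO replicate 1 (0.100) or KO replicate 2 (0.0514), and Skil without WT replicate 2 (0.0995) or KO replicate 1 (0.132).

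Naive pluripotency genes moved in both directions. Of 20 tested, 2 rose and 3 fell, and the same numbers passed when adjusted over the list alone. Klf4, a transcription factor of the naive state, was 3.02-fold lower in KO cells (140 ± 30.5 against 423 ± 107 CPM, adjusted p = 0.00103), and Tbx3 was 2.01-fold lower (187 ± 15.9 against 377 ± 51.8 CPM), while Klf2 rose by 0.94 (SE 0.25). The Tbx3 call was lost without WT replicate 1 (adjusted p = 0.0977), KO replicate 1 (0.153) or KO replicate 2 (0.0776), and that of Klf2 without WT replicate 2 (0.256), KO replicate 1 (0.132) or KO replicate 2 (0.149). Of 14 primed or formative genes, 2 rose and 2 fell (4 and 4 adjusted over the list alone). The WNT effector gene Lef1 was 11.8-fold higher, the transcription factor gene Sox4 3.38-fold lower and the carbonic anhydrase gene Car4 10.4-fold lower in KO cells. Camera called neither list (adjusted p = 0.897 for naive and 0.626 for primed genes).

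Genes of the integrated stress response and amino acid synthesis rose in KO cells, and cholesterol synthesis genes fell. Of 14 members of the first list, 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 2.49e-06; adjusted p = 0.224 with an estimated correlation). Slc7a11, the cystine importer subunit, was 17.4-fold higher in KO cells (77.6 ± 0.45 against 4.52 ± 2.25 CPM). Shmt2, a mitochondrial serine hydroxymethyltransferase gene that overlaps Ndufa4l2 on the other strand, was 2.61-fold higher, and the pseudokinase gene Trib3 2.57-fold. The Trib3 call was lost without WT replicate 1 (adjusted p = 0.0580). Of 16 cholesterol genes, 6 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000821; adjusted p = 0.224 with an estimated correlation). The sterol-sensing regulator Insig1 fell by 1.42 (SE 0.29) and the enzyme gene Msmo1 by 0.91 (SE 0.22). Insig1 lost its call without WT replicate 2 (adjusted p = 0.0530) or KO replicate 1 (0.0900), and Msmo1 without any 1 of the 4 libraries (0.0626 to 0.153).

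Several other lists were called by camera with the preset correlation and not with an estimated one. None of 16 MYC targets and ribosome biogenesis genes changed (0 rose and 0 fell, also adjusted over the list alone), yet the list shifted down by a median log2 fold change of -0.35. Npm1 was at -0.32 (SE 0.23) and Ncl at 0.02 (SE 0.23). Its camera adjusted p was 0.0133 (adjusted p = 0.449 with an estimated correlation), 0.0725 with fry, and 0.125 without WT replicate 1 or 0.0621 without KO replicate 2. Of 16 p53 targets, 3 fell and 1 rose (4 and 1 adjusted over the list alone). Btg2, the polo-like kinase gene Plk2 (-1.61, SE 0.39) and the stress gene Trp53inp1 (-1.20, SE 0.28) fell. Over the leave-outs Plk2 ran from -2.13 to -0.74 and Trp53inp1 from -1.57 to -0.70. The camera adjusted p was 0.0142 (adjusted p = 0.471 with an estimated correlation), 0.167 with fry, and 0.325 without WT replicate 1. The gene calls were lost without WT replicate 1 (adjusted p = 0.0663 for Btg2, 0.344 for Plk2 and 0.199 for Trp53inp1), KO replicate 1 (0.100, 0.130 and 0.0539) or KO replicate 2 (0.0514, 0.0742 and 0.133). Of 11 epithelial markers, 3 rose and 0 fell, also adjusted over the list alone. The splicing regulator Esrp1 was 7.27-fold higher (54.6 ± 18.4 against 7.49 ± 0.32 CPM), and the list's camera adjusted p was 0.0336 (adjusted p = 0.265 with an estimated correlation; 0.0184 with fry and 0.129 without WT replicate 1). Of 10 DNA methylation genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone). Dnmt3l, a cofactor of de novo methyltransferases, was 3.79-fold lower (63.5 ± 0.25 against 241 ± 41.1 CPM), and Zfp57, which protects imprints, fell by 1.65 (SE 0.34; adjusted p = 0.0980 without KO replicate 1). That list's camera adjusted p was 0.0336 (adjusted p = 0.471 with an estimated correlation; 0.141 with fry and 0.172 without WT replicate 1).

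The remaining lists were not called by camera. Of 20 G1/S genes, 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0577), and cyclin D2 (Ccnd2) was 26.5-fold higher in KO cells (439 ± 54.8 against 16.5 ± 1.19 CPM). The G1/S list was called without WT replicate 1 (adjusted p = 0.0452) or KO replicate 1 (0.0336), on the 4 libraries of this set alone (0.0479) and with fry (0.0280). Of 17 imprinted genes, 5 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.614), with Peg3 3.67-fold higher and Phlda2 5.30-fold lower. Of 9 interferon response genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0981). These were Oasl2, with 60 and 42 counts in KO and 0 in WT libraries, and Ifit1, with 13 and 22 against 0. Against a floor of 3 counts over the WT group they were at least 30.7-fold and at least 10.5-fold higher. The Ifit1 call was lost without WT replicate 1 (0.0789), WT replicate 2 (0.0636) or KO replicate 2 (0.0603), and the list was called without KO replicate 1 (0.0223) and with fry (0.0184). Its median of -0.04 had the opposite sign to its mean of 2.00 and to the test's direction. Of 12 WNT targets, 4 rose and 1 fell (4 and 4 adjusted over the list alone; adjusted p = 0.614), and the median of -0.44 had the opposite sign to the test's direction.

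Of 14 microRNA pathway genes, 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.614). These were Ago1, an Argonaute gene (0.99, SE 0.25), Lin28a (-0.84, SE 0.24) and Trim71 (-0.72, SE 0.22), and each call was lost without any 1 of the 4 libraries (adjusted p up to 0.201, 0.370 and 0.321). Trim71 was also not called with no filter on low counts (0.0701). Of 15 glycolysis genes, 0 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0981). This was the phosphoglycerate mutase gene Pgam1 (-1.06, SE 0.27), whose call was lost without any 1 of the 4 libraries (adjusted p 0.0547 to 0.218), and the list was called lower without WT replicate 1 (0.0425) or KO replicate 1 (0.030). Of 11 mesenchymal markers, 0 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.497), with a median of 0.02 against a test direction of down. None of 10 genes reported to respond to TFAP4 changed (0 also when adjusted over the list alone; adjusted p = 0.723), and the abundant members Fn1 and Cdh1 were at 0.18 (SE 0.30) and 0.09 (SE 0.22). Among markers of other cell states, Zscan4d of the 2-cell-like state rose (3.06, SE 0.74), 1 of 3 tested, but 55.3% of its last 200 bases are shared with other genes. Of 4 fibroblast or feeder genes Thy1 (-1.35, SE 0.36) and Col1a1 (-2.20, SE 0.66) fell. Both lists were too short for a list test, and adjusted over the list alone they held 2 rises and 2 falls. The Zscan4d call was lost without WT replicate 1 (adjusted p = 0.0952), WT replicate 2 (0.0698) or KO replicate 2 (0.175), that of Thy1 without WT replicate 2 (0.261) or KO replicate 1 (0.294), and that of Col1a1 without any 1 of the 4 libraries (0.124 to 0.219). Col1a1 was also not called with DESeq2 (0.223), limma-voom (0.0850), the legacy fit (0.107) or no filter on low counts (0.0525), nor Thy1 on the 4 libraries of this set alone (0.0561).

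**Figure D2:**
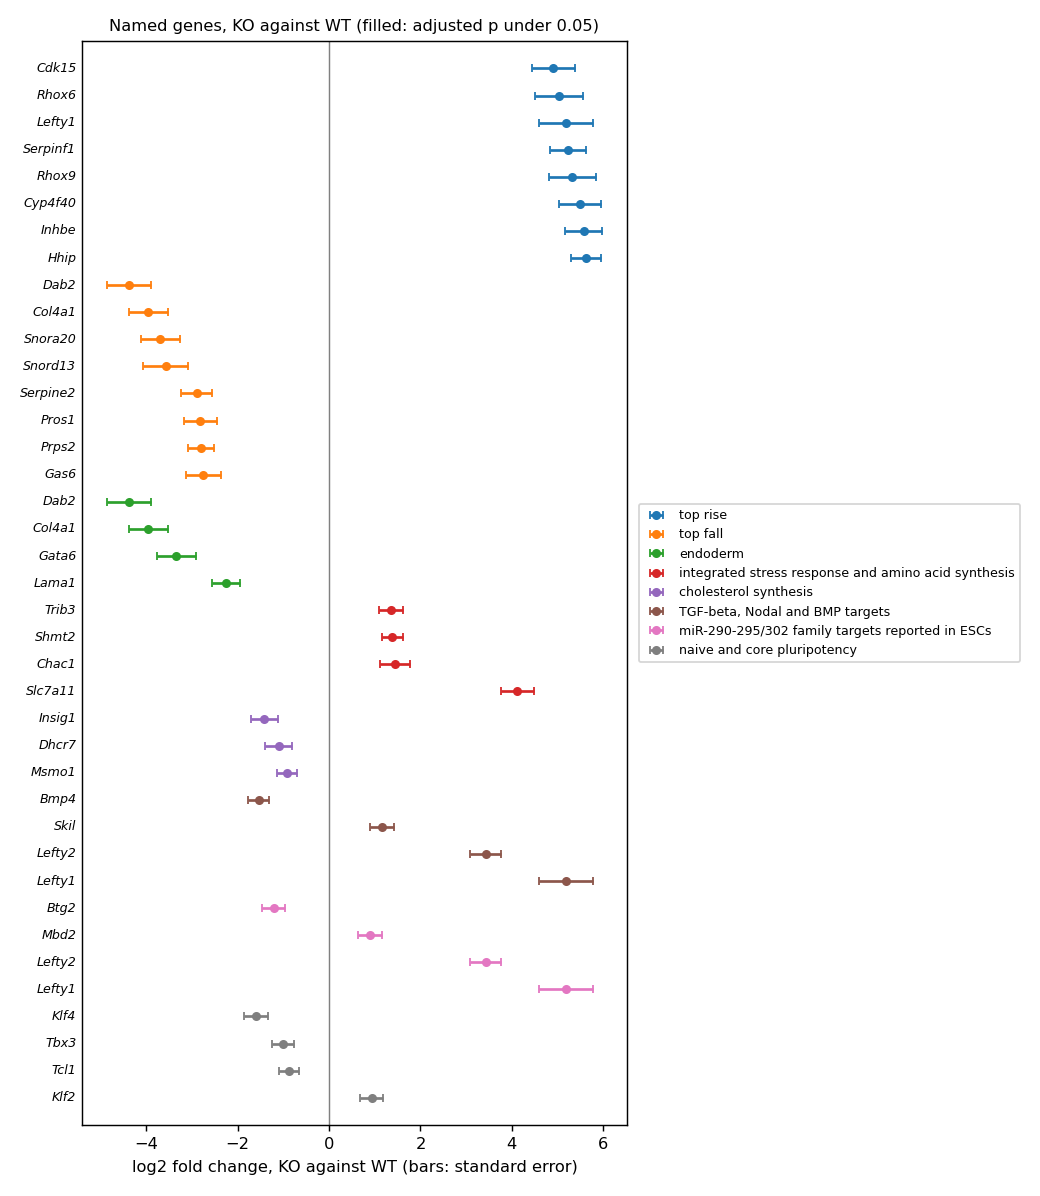
Log2 fold change of named genes between KO and WT cells, with bars of 1 standard error, coloured by the rule or list that named them, so that a gene named by more than one appears more than once. Hhip reached 5.62 and Dab2 fell to -4.39, and filled points mark an adjusted p under 0.05 in edgeR.

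Genes carrying sites for the cluster's shared seed were slightly higher in KO cells. The 2763 tested genes with AGCACTT or GCACTTA in the longest annotated 3′ UTR had a median log2 fold change of 0.09, against -0.04 for the 8349 genes without any site, a difference of 0.13. Camera gave p = 0.0393 for the genes with a site, and p = 0.128 with an estimated correlation. The p was 0.0742 without WT replicate 2 and 0.0755 without KO replicate 2, and 0.0705 with the correction for base composition. In a linear model across genes with 3′ UTR length and GC as covariates, GCACTTA had the highest rank of 15958 words of this length (coefficient 0.162, SE 0.030) and AGCACTT followed at rank 2 (0.0897, SE 0.023). AAGGCAC stood at rank 3 (0.108, SE 0.027), with a coefficient over SE of 3.979 against 3.980 for AGCACTT. The seed match of miR-290a-3p and miR-292a-3p, GGCACTT, stood at rank 160 (0.0662, SE 0.028). With squared covariates, a model added after seeing the data, GCACTTA stayed at rank 1 (0.165, SE 0.030), AAGGCAC, which does not hold the 6mer GCACTT, took rank 2 (0.110, SE 0.027), and AGCACTT stood at rank 3 (0.0913, SE 0.023). The shift was 0.276 (SE 0.045) for 459 genes with the 8mer AGCACTTA, 0.134 (SE 0.046) for 430 genes with GCACTTA alone, 0.0684 (SE 0.025) for 1874 genes with AGCACTT alone and 0.0383 (SE 0.026) for 1668 genes with the 6mer alone. Genes are not independent replicates in this model. In siTfap4 against siNeg, where the cluster is absent from both groups, the genes with a site differed from those without by -0.06 and were not called by camera, and AGCACTT and GCACTTA ranked 2576 and 9901. There the difference was -0.13 without siNeg replicate 2, and it turned to 0.01 without siNeg replicate 1 and to 0.04 with the correction for base composition, against 0.13 in KO against WT with that correction. The shift of genes with AGCACTT alone was 0.0562 (SE 0.026) in this comparison. CAATAAA ranked 1 there, with a coefficient over SE of 7.97, above the 5.37 of GCACTTA in KO against WT. High values in this model thus also arise where the cluster is absent from both groups.

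**Figure D3:**
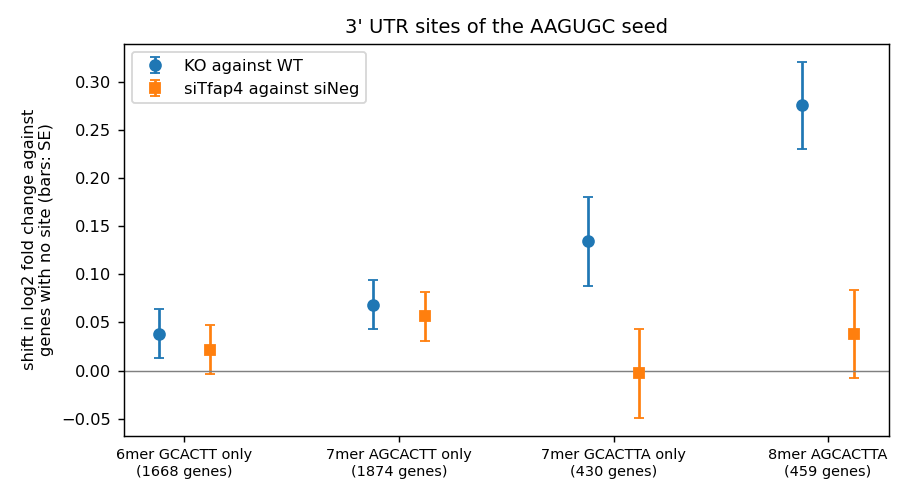
Shift in log2 fold change of genes with each class of 3′ UTR site relative to genes without any, from a linear model with 3′ UTR length and GC, with bars of 1 standard error. In KO against WT the shift was 0.276 for the 8mer and 0.0383 for the 6mer alone, while the 8mer shift in siTfap4 against siNeg was 0.0382.

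The comparison of siTfap4 with siNeg asks which transcripts of KO cells change when Tfap4 is lowered. Among the largest falls, Dppa5a, an RNA-binding protein gene of pluripotent cells, was 66.3-fold lower (6.57 ± 3.89 against 440 ± 74.7 CPM) and the nuclear receptor gene Nr0b1 26.2-fold lower (3.71 ± 3.09 against 98.6 ± 80.7 CPM). Nanog was 2.82-fold lower (129 ± 69.9 against 364 ± 67.4 CPM). Ctnnd1, which encodes p120 catenin, was 42.6-fold lower (2.34 ± 0.30 against 99.6 ± 78.6 CPM) and Txnip, a glucose-responsive regulator, 29.5-fold lower (10.9 ± 2.96 against 322 ± 62.2 CPM). The rises of well-expressed genes whose groups did not overlap were smaller. The largest was that of the small nucleolar RNA gene Snord89 (4.03-fold, 28.0 ± 3.06 against 6.92 ± 1.85 CPM), and Dstn, an actin-depolymerising protein gene, was among the others (3.02-fold, 1338 ± 413 against 442 ± 59.0 CPM).

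In edgeR, 2334 of 15137 genes differed: 660 rose and 1674 fell, so that 28.3% of the calls were rises. The count was 732 without siNeg replicate 1 (34 rises and 698 falls), 499 without siTfap4 replicate 1 (12 and 487), 1978 without siNeg replicate 2 and 2987 without siTfap4 replicate 2. When the 4 libraries of this set were fitted alone, 324 genes rose and 1469 fell, so that the rises were 18.1% of 1793 calls. The other large falls were Pfn1, the actin-binding profilin (log2 fold change -5.59, SE 0.79), Pmpcb, a subunit of the mitochondrial processing peptidase (-5.25, SE 0.71), the F-box gene Fbxl14 (-5.11, SE 0.61) and the snoRNA host gene Snhg8 (-4.77, SE 0.48). Other large rises were Serpine2 (1.72, SE 0.36), the desmosomal gene Pkp3 (1.69, SE 0.34), Tex19.2 (1.58, SE 0.36), the mitochondrial enzyme genes Clybl (1.57, SE 0.33) and Acads (1.48, SE 0.29), and Klc3, a kinesin light chain gene that overlaps Ercc2 on the other strand (1.52, SE 0.33). Adjusted p-values ran from 1.40e-07 for Dppa5a to 0.00225 for Nr0b1 among the 8 largest falls, and from 0.000991 for Dstn to 0.00832 for Tex19.2 among the 8 largest rises. Without siNeg replicate 1 the calls of Serpine2 (adjusted p = 0.0631), Pkp3 (0.0841), Tex19.2 (0.108), Klc3 (0.0777), Acads (0.0614) and Nanog (0.0620) were lost. Without siTfap4 replicate 1 those of Pkp3 (0.103), Tex19.2 (0.0794), Clybl (0.126), Klc3 (0.0772), Acads (0.0686) and Nr0b1 (0.0606) were lost, and that of Clybl was also lost without siNeg replicate 2 (0.0563). With no filter on low counts Pmpcb (0.0544) and Nr0b1 (0.0843) were not called. Of the last 200 bases of Dppa5a, 39.4% are shared with other genes.

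Fold changes in this comparison followed the base composition of the transcripts' 3′ ends. Across genes, the GC percent of the last 100 bases had a Spearman correlation of 0.394 with the log2 fold change of siTfap4 against siNeg and of -0.031 with that of KO against WT. In the decile of genes with the lowest GC (median 23%), 26.3% fell and 1.13% rose, and in the highest decile (median 55%), 4.26% fell and 9.94% rose. The level of a gene relative to its mean over libraries had a correlation with GC of 0.351 and 0.340 in the siTfap4 libraries, -0.291 in siNeg replicate 1 and 0.0758 in siNeg replicate 2. With a correction for this trend, 1872 genes were called (618 rose and 1254 fell). Of the 1674 genes that fell without it, 67.6% still fell, and of the 660 that rose, 39.1% still rose. Of the 62 called named genes of this comparison other than Tfap4, 14 were not called with it. Only some of these 14 are pointed out where they are named. Of 8 transcripts of the mitochondrial genome, mt-Cytb fell by 1.57 (SE 0.32, adjusted p = 0.00454), and the other 7, from mt-Nd3 at -2.16 (SE 1.30) to mt-Nd2 at 0.96 (SE 0.38), were not called. With the correction mt-Nd5 was called as well (0.72, adjusted p = 0.0366).

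**Figure D4:**
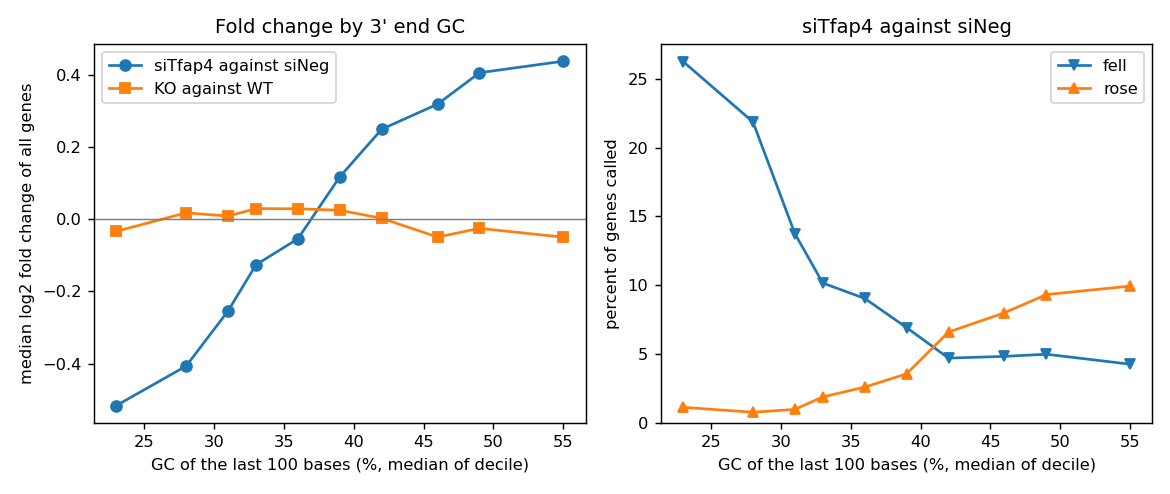
Left, median log2 fold change of the tested genes in 10 bins of 3′ end GC percent for both comparisons; right, percent of genes called as fallen or risen in siTfap4 against siNeg. In the bin with the lowest GC 26.3% of genes fell, and in the highest 4.26%.

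WNT targets were the sole list that camera called in siTfap4 against siNeg (adjusted p = 0.00803; adjusted p = 0.437 with an estimated correlation). Of 12 members, 5 fell and 0 rose, also adjusted over the list alone, and with the correction for base composition 3 fell and 1 rose. Tcf7, a WNT effector gene, was 11.9-fold lower (1.65 ± 0.004 against 19.8 ± 0.29 CPM), Notum, a secreted WNT inhibitor gene, 19.1-fold lower (3.54 ± 2.84 against 68.4 ± 65.1 CPM), and cyclin D1 (Ccnd1), which overlaps LTO1 on the other strand, 2.44-fold lower (94.5 ± 16.4 against 230 ± 14.3 CPM). The list's camera adjusted p was 0.0865 without siTfap4 replicate 2 and 0.196 with the correction for base composition. The median GC of its members' 3′ ends was 27%. Tcf7 kept its call without any 1 library, Notum lost it without siTfap4 replicate 1 (adjusted p = 0.144) and with no filter on low counts (0.138), and Ccnd1 lost it without siNeg replicate 1 (0.0580) or siTfap4 replicate 1 (0.134).

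The list of naive pluripotency genes held 4 falls and 1 rise among 20 members (5 and 1 adjusted over the list alone; camera adjusted p = 0.160, and 0.0306 with fry). Besides Dppa5a, Nr0b1 and Nanog, the cytokine signalling inhibitor Socs3 was 11.1-fold lower (12.6 ± 11.5 against 141 ± 61.8 CPM; adjusted p = 0.00538, and 0.122 with no filter on low counts). Of 14 primed genes, 1 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.995): Foxd3, a transcription factor gene, was 5.90-fold lower. Among 10 genes reported to respond to TFAP4, 1 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.995). Camera tests for a shift in 1 direction, so members that move in opposite directions can cancel. With the direction-free test of fry the adjusted p was 0.000221, and 0.0734 in KO against WT. That test was passed in siTfap4 against siNeg by other lists too, such as glycolysis (0.000175). It was not run with the correction for base composition. The intermediate filament gene Vim (-1.59, SE 0.23), the replication licensing inhibitor Gmnn (-1.51, SE 0.27) and the transcription factor gene Snai1 (-2.34, SE 0.57) fell. Cdkn1a, the cell cycle inhibitor p21, rose by 1.02 (SE 0.23). Of 20 G1/S genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone; adjusted p = 0.995), with Cdk2 3.32-fold lower and E2f2 2.12-fold higher. With the correction for base composition, rises and falls numbered 2 and 4 for G1/S, 0 and 2 for genes reported to respond to TFAP4, 2 and 5 for naive and 1 and 1 for primed genes, and Cdkn1a (0.69, adjusted p = 0.0546) and Snai1 (-1.76, adjusted p = 0.0529) were not called. Nanog lost its call without siNeg replicate 1 (adjusted p = 0.0620) and Nr0b1 without siTfap4 replicate 1 (0.0606). E2f2 lost its call without siNeg replicate 1 (0.0532) or siTfap4 replicate 1 (0.0804), and Snai1 without siNeg replicate 1 (0.0976) or siTfap4 replicate 1 (0.181).

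Metabolic and microRNA lists held both rises and falls, in part only before the correction for base composition. Of 15 glycolysis genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone). Gapdh was 7.44-fold lower (17.5 ± 0.96 against 131 ± 12.1 CPM), but 85.9% of its last 200 bases are shared with other genes, so its value is uncertain. The glucose transporter gene Slc2a1 was 2.47-fold lower. Of 14 stress response and amino acid genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone), with the serine synthesis gene Phgdh 6.10-fold lower and 26.5% of its end shared. Of 19 reported targets of the microRNA family, 2 rose and 3 fell, also adjusted over the list alone, and Mbd2 was 3.92-fold lower. Of 16 MYC and ribosome biogenesis genes, 1 rose and 2 fell, also adjusted over the list alone, with the helicase gene Ddx18 2.73-fold lower. Of 16 cholesterol genes, 1 rose and 1 fell. Of 14 microRNA pathway genes, 1 rose and 1 fell, the latter Xpo5, which exports microRNA precursors (2.43-fold lower). Of 16 p53 targets, 1 rose and 1 fell. Adjusted over the list alone, the last 3 lists had the same counts. With the correction for base composition, rises and falls numbered 1 and 3 for glycolysis, 0 and 2 for stress response and amino acids, 0 and 2 for the reported targets, 1 and 0 for cholesterol and 0 and 1 for p53 targets. The MYC and microRNA pathway lists then had the same counts as before. Camera gave an adjusted p of 0.995 for each of these 7 lists.

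Camera called no lineage list, and over all 15137 tested genes 2334 were called. None of 13 endoderm genes was called (0 also when adjusted over the list alone; Sparc at 0.40, SE 0.28), nor any of 17 imprinted genes (Meg3 at 0.77, SE 0.41; called without siTfap4 replicate 2 at 1.25, adjusted p = 0.0392) or 9 interferon response genes (Ddx58 at 0.68, SE 0.34). None of 6 neural genes was called (1 up and 1 down adjusted over the list alone). Among them Sox11 was at 0.73, and from 0.05 to 1.22 over the leave-outs. Of 11 trophectoderm genes 2 fell, among them the surface protein gene Plet1 (3.36-fold lower). Of 5 mesoderm genes 1 fell, of 14 TGF-beta, Nodal and BMP genes 3 fell, of 11 mesenchymal markers 2 fell, of 11 epithelial markers 1 fell and of 10 DNA methylation genes 1 fell, and none of these rose. Adjusted over the list alone these counts were the same, except that 1 epithelial marker then rose. With the correction for base composition, 1 trophectoderm gene, 0 mesoderm genes, 1 TGF-beta, Nodal or BMP gene and 1 mesenchymal marker fell and none of these rose, while 1 epithelial marker rose and 2 fell, and 1 DNA methylation gene rose and 1 fell. Camera adjusted p was 0.709 for the TGF-beta list and 0.995 for the others. The median and the test direction differed in sign for trophectoderm, endoderm, neural, mesenchymal, epithelial and cholesterol genes and the reported targets of the microRNA family. The mean and the test direction differed in sign for endoderm, neural, epithelial, cholesterol, G1/S, MYC, glycolysis and stress response genes. None of 3 tested genes of the 2-cell-like state and none of 4 fibroblast or feeder genes was called, also adjusted over the list alone.

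**Figure D5:**
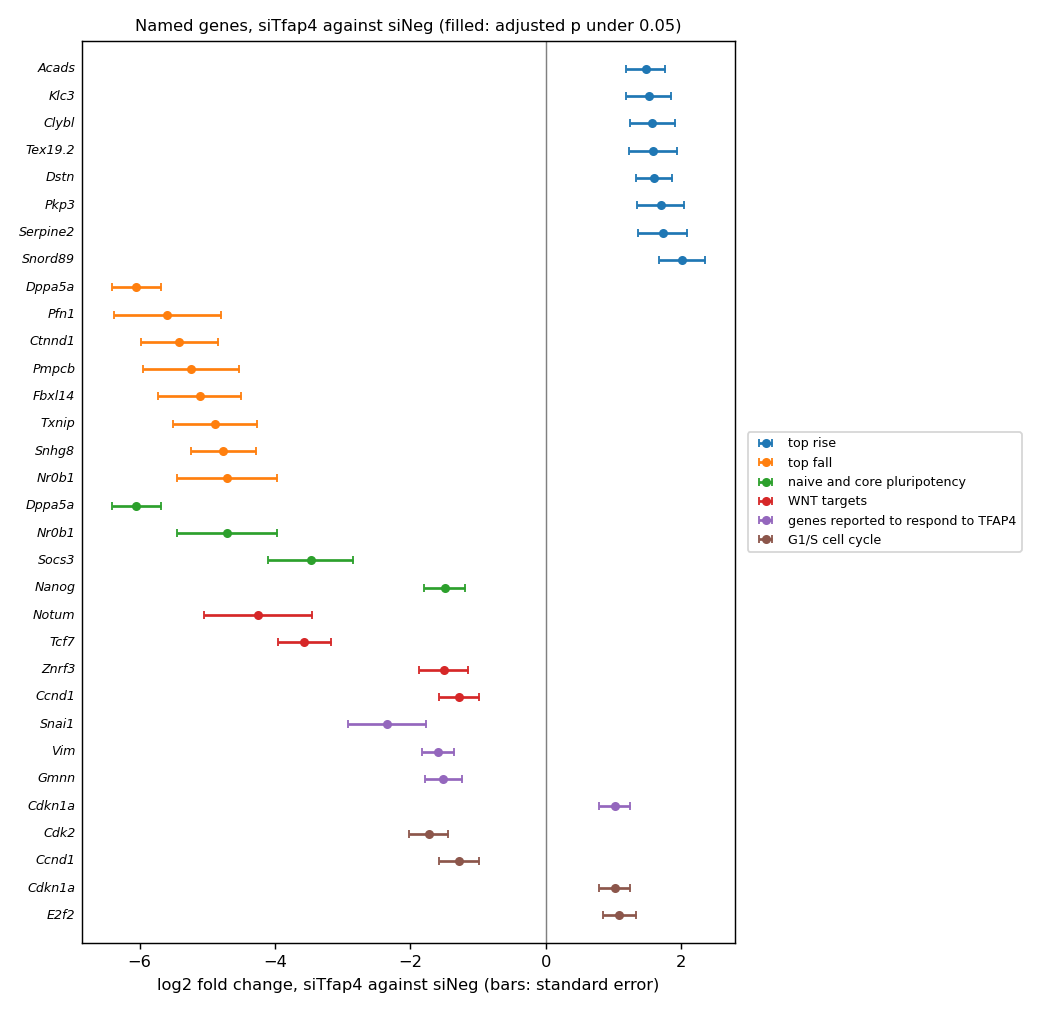
Log2 fold change of named genes between siTfap4 and siNeg, with bars of 1 standard error, coloured by the rule or list that named them, so that a gene named by more than one appears more than once, and with filled points for an adjusted p under 0.05 in edgeR. Dppa5a fell to -6.05 and the largest rise called among the genes shown, Snord89, was 2.01.

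The last comparison asks whether genes that rose in KO cells fell when Tfap4 was lowered, and the reverse. Notum, the WNT inhibitor gene, rose by 3.15 (SE 0.69) in KO cells and fell by 4.25 (SE 0.80) after the Tfap4 pool, and Fam167a rose by 3.30 (SE 0.38) and fell by 2.68 (SE 0.44). The other genes with the largest opposite changes were G0s2, a lipolysis inhibitor gene (2.88 and -3.09), Igfbp7, an insulin-like growth factor binding protein gene that overlaps Polr2b on the other strand (2.65 and -3.51), and the secreted factors Fgf21 (2.84 and -4.07) and Osm (2.69 and -4.38). Over the leave-outs Osm ran from 1.82 to 7.79 in KO against WT and from -7.96 to -3.13 in siTfap4 against siNeg. Fgf21 ran from 2.09 to 4.08 and from -7.65 to -2.36. Of the 907 genes that rose in KO cells, 117 fell with siTfap4, against 100.3 for independent lists (odds ratio 1.21, 95% interval 0.977 to 1.48, Fisher's exact test, two-sided, p = 0.0715). Of the 599 that fell in KO cells, 19 rose, against 26.1 (odds ratio 0.710, exact p = 0.183). In the same direction, 32 genes rose in both, against 39.5 (odds ratio 0.792, exact p = 0.240), and 28 fell in both, against 66.2 (odds ratio 0.384, exact p = 2.62e-08). These exact p-values assume independent lists, but both comparisons were called in a joint model that shares each gene's dispersion. Across genes, the fold changes of both comparisons had a Pearson correlation of -0.031 and a Spearman correlation of -0.048. Over the leave-outs the Pearson correlation ran from -0.069 without siNeg replicate 1 to 0.0069 without siTfap4 replicate 1. The Spearman correlation ran from -0.081 without KO replicate 2 to 0.0036 without WT replicate 2. Fitting each comparison on its own 4 libraries moved the first odds ratio to 1.41 (exact p = 0.000272) and ended the last call (0.892, exact p = 0.463), over 13243 genes tested in both. The odds ratio of rising in both then turned to 1.14 (exact p = 0.525). The odds ratio of falling in both was 0.194 without WT replicate 1, 0.190 without KO replicate 2 and 0.0971 without siTfap4 replicate 1. That of falling in KO and rising with siTfap4 was 0.396 without KO replicate 1 (exact p = 0.125), 1.52 without siNeg replicate 1 (exact p = 0.392) and 2.21 without siTfap4 replicate 1 (exact p = 0.384). It passed the threshold without siNeg replicate 2 (0.547, exact p = 0.0451) or siTfap4 replicate 2 (0.649, exact p = 0.0208), and so did rising in both without siNeg replicate 2 (0.588, exact p = 0.0258). Rising in both was at 0.475 without siNeg replicate 1, where 1 gene did so, at 0 without siTfap4 replicate 1, where 0 did, and at 1.04 without KO replicate 1. With DESeq2, falling in KO and rising with siTfap4 was at 1.14 (exact p = 0.450).

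Of the genes with opposite changes, Fam167a kept both calls without any 1 library and Igfbp7 kept its rise in KO cells. In KO against WT, G0s2 (adjusted p = 0.179), Notum (0.0967) and Fgf21 (0.226) were not called without WT replicate 1, nor were Notum (0.200), Fgf21 (0.0566) and Osm (0.250) without WT replicate 2. Without KO replicate 1 the calls of G0s2 (0.125), Notum (0.0874), Fgf21 (0.181) and Osm (0.196) were lost, and without KO replicate 2 those of G0s2 (0.0783), Notum (0.0617) and Osm (0.0831). In siTfap4 against siNeg, G0s2 (0.0508), Igfbp7 (0.102), Notum (0.144), Fgf21 (0.276) and Osm (0.217) were not called without siTfap4 replicate 1. Fgf21 (0.385) and Osm (0.233) were also not called without siNeg replicate 1, nor Fgf21 (0.0716) and Osm (0.0523) without siTfap4 replicate 2. With no filter on low counts, G0s2 (0.267) and Notum (0.234) were not called in KO against WT, nor were they in siTfap4 against siNeg (0.202 and 0.138). With the correction for base composition Fgf21 was not called in siTfap4 against siNeg (0.0608). Other tests also ended calls in KO against WT: DESeq2 those of G0s2 (0.0632) and Osm (0.0624), the legacy fit those of G0s2 (0.0583), Fgf21 (0.0622) and Osm (0.0944), and limma-voom those of Fgf21 (0.0570) and Osm (0.0530). In siTfap4 against siNeg, Fgf21 was not called with limma-voom (0.0661), nor G0s2 on the 4 libraries of that set alone (0.0693).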

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

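The correction for base composition, alone or with the replicate block, and the model with squared covariates were chosen after the result was seen, and the other settings were not. No called named gene reversed its direction in any setting run, while the uncalled Fn1, Cdh1, Ncl and AU018091 took either sign in KO against WT, and Lamb1, Zdbf2 and Zscan4c in siTfap4 against siNeg. Of 79 called named genes in KO against WT, 36 kept their call without any 1 library, and of 62 in siTfap4 against siNeg, 24 did. Leaving out 1 library gave 610 to 857 genes in KO against WT and 499 to 2987 in siTfap4 against siNeg, with fewer residual degrees of freedom, and a threshold of 0.1 gave 3528 in the latter. The log2 fold change of Tfap4 ranged over the leave-outs from 1.21 to 1.48 and from -1.54 to -1.18, and the latter was -1.07 with the correction for base composition, alone or with the replicate block. With an estimated correlation 0 lists were called in KO against WT and 0 in siTfap4 against siNeg, where fry called 2, the correction for base composition 0, that correction with the replicate block 0, and the leave-outs 0 to 1. The p of genes with a seed site was 0.128 with an estimated correlation, 0.0533 for AGCACTT alone, 0.0627 for the 6mer, 0.0942 for GGCACTT, 0.0504 over all annotated 3′ UTRs, 0.0705 with the correction for base composition, 0.0692 with that and the replicate block, and 0.0380 to 0.0755 over the leave-outs. The odds ratio of rising in KO and falling in siTfap4 was 0.995 with DESeq2, 1.41 on each comparison's own 4 libraries, 0.997 with the correction for base composition and 0.886 to 1.30 over the leave-outs. The cause was not tested in any of these cases. With the replicate number as a block, 1337 and 2064 genes were called, against 1506 and 2334 without it. Of the called named genes, Mbd2 (adjusted p = 0.0641), Col1a1 (0.0758), Trim71 (0.0516), Osm (0.0554) and Ei24 (0.0523) were then not called in KO against WT, nor were Fgf21 (0.0517), Slc7a11 (0.0686) and Wdr43 (0.0570) in siTfap4 against siNeg. A crossed block, which joins WT replicate 1 and KO replicate 2, whose titles share a suffix of unstated meaning, and sets the other 2 libraries together, gave 1791 in KO against WT. Replicate differences of the paired groups had a correlation across genes, which are not independent replicates, of -0.061 and 0.126. The search for E-boxes and its alternatives were not run. Depth and 2 libraries per group limit what small changes can be called.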

Other observations

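The families, the test of base composition, the test of a library difference, that of the Tfap4 level and that of 3′ UTR length were chosen after the result was seen. Counts assigned to small nucleolar RNA genes were lower in KO than in WT cells. The libraries hold 3′ ends of polyadenylated RNA, and which transcripts gave these counts was not tested. Of 29 such genes tested, 12 fell and 0 rose, with a median log2 fold change of -1.75, Snora20 at -3.70 and Snord13 at -3.58. Over the leave-outs the median ran from -2.53 without KO replicate 1 to -1.39 without WT replicate 2. Camera over 14 families gave an adjusted p of 2.07e-12 (adjusted p = 0.0171 with an estimated correlation; 0.0752 without WT replicate 2, 0.0811 without KO replicate 1 and 0.103 without KO replicate 2). Together these genes held 380 and 502 CPM in the WT libraries and 178 and 172 CPM in KO, 118 and 186 CPM in siNeg, and 202 and 220 CPM in siTfap4. These CPM are not scaled with TMM factors. Collagen genes fell in 4 of 19 cases and rose in 2, led by Col4a1 (adjusted p = 0.0468; adjusted p = 0.333 with an estimated correlation). Of 11 keratin genes 3 rose and 0 fell, and of 12 serpin genes 3 rose and 1 fell, each list with an adjusted p of 0.0119 (adjusted p = 0.333 with an estimated correlation). Of 6 Rhox homeobox genes 2 rose and 1 fell (adjusted p = 0.0119; adjusted p = 0.30 with an estimated correlation). Of 46 histone genes 0 rose and 1 fell, with a median of -0.60 (adjusted p = 0.0119; adjusted p = 0.614 with an estimated correlation).

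In siTfap4 against siNeg, cytosolic ribosomal protein genes fell in 19 of 79 cases and rose in 4 (adjusted p = 0.0281; adjusted p = 0.996 with an estimated correlation). The median share of their last 200 bases found in other genes was 37.1%, and with the correction for base composition 17 fell and 2 rose. Of 46 histone genes 5 rose and 0 fell (adjusted p = 0.000444; adjusted p = 0.996 with an estimated correlation), and 2 rose with the correction for base composition. Of 29 small nucleolar RNA genes 2 rose and 1 fell (camera adjusted p = 0.0381, and 0.604 with an estimated correlation), and with that correction 1 rose and 0 fell.

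More genes fell (1674) than rose (660) in siTfap4 against siNeg. The tables argue against lower depth, since 1692 genes fell after all libraries were thinned to 8326675 counts. With the correction for base composition 67.6% of the falls were still called. This argues against the fitted trend in GC of the last 100 bases as the whole cause. Calls still followed GC after it: 209 of 1599 genes fell and 152 rose in the lowest decile, and 100 of 1479 fell and 22 rose in the highest. Other effects of base composition are therefore not excluded. The genes that fell had a median log2 fold change of -1.52 here and 0.0530 (SD 0.660) in KO against WT. Tfap4 differed by a similar factor there. These genes were chosen by their fall, and KO differs from WT in the cluster too. The values therefore cannot decide whether the lower Tfap4 level was the whole cause. A difference between libraries not tied to the Tfap4 level stays open: the median of siNeg replicate 2 minus replicate 1 was -0.224 among the fallen genes and -0.0338 among all, while Tfap4 was at 34.4 and 37.4 CPM in these libraries. An effect of the Tfap4 siPOOL that the KO comparison does not share stays open too, as untested.

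Genes with a seed site were higher in KO cells. The tables argue against 3′ UTR length or GC, since GCACTTA kept a coefficient of 0.162 with both as covariates. With these covariates, the largest 8mer coefficient in size among the 4 replicate differences was -0.0389, against 0.276 in KO against WT. For GCACTTA alone, siNeg replicate 2 minus replicate 1 reached 0.0538, against 0.134 in KO against WT. The replicate differences used log2 CPM and the KO coefficients edgeR fold changes. They argue against variation between duplicates as the source of the 8mer coefficient. They cannot show a shift between the WT and KO groups that is unrelated to the cluster. Nor do they cover unadjusted values, on which the list test rests: in siNeg replicate 2 minus replicate 1 the median of 8mer genes was -0.16, against 0.03 without a site. The excess of the 8mer over the 6mer was 0.237 (SE 0.0485), which is consistent with loss of repression by the cluster's microRNAs. This remains a hypothesis, since the list test missed its threshold in several settings (p = 0.128 with an estimated correlation); with the correction for base composition its p was 0.0705, slightly above that of siTfap4 against siNeg, where the cluster is absent, and the shift of genes with AGCACTT alone was 0.0684 here and 0.0562 there.

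Few genes fell in both comparisons (28, against 66.2 for independent lists). Of the genes that fell in KO cells, 29.5% had fewer than 1 CPM in the siPOOL libraries, against 10.5% of all tested genes. Stratified by level the odds ratio was 0.480 (95% interval 0.325 to 0.707), and with the correction for base composition it was 0.553 (0.370 to 0.797). Within the joint fit these values argue against low levels, and against the fitted trend in 3′ end GC, as the whole cause. On each comparison's own 4 libraries the odds ratio was 0.892 (exact p = 0.463). That setting shares no dispersions between the comparisons and also changes which genes are tested. There 60 genes fell in both, against 66.2 for independent lists. Since 28 did so in the joint fit, changed calls, and not only dropped genes, ended the depletion. Why the calls changed was not separated, and the cause of the depletion in the joint fit stays open.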
